A study of Homo sapiens with 12 samples.

How the data were processed

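Total RNA of PC3-ML and LNCaP cells was labelled as biotinylated cRNA and hybridised to Illumina HumanHT-12 v4 arrays, 1 array per sample, 12 in all. Per the labels, PC3-ML cells were transduced on 2 consecutive nights and left 48 hours to recover, cultures above 95% transduction efficiency were used, and LNCaP cells were harvested 48 hours after transfection. The submitters' processing notes name GenomeStudio 1.9.0.

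Per the file headers, the deposited non-normalized table holds bead intensity without background subtraction or normalization, with the SD over beads, the number of beads (median 22 or 23 per probe on each array) and a detection score in other units. That score rose with the signal in steps of the 770 negative control probes and was read as 1 minus the detection p-value. A deposited control table gives the intensity and detection p-value of the negative and other control probes. The deposited series values for 22500 probes are intensity on a linear scale with a constant per array subtracted (between 73.6 and 85.4) and a floor, and the 239190 values of the per-line tables equal them. Which probes the authors kept is not stated. The authors also deposited a p-value and a ratio of group means (fold) per probe for each cell line, 20091 probes in PC3-ML and 19774 in LNCaP, by a test they do not name. The ratios of MIR23B and MIR27B in that table, 16962 and 11707, divide by values at or near the floor and were not used.

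Signals were processed with limma 3.58.1 in R 4.3.3, with statmod 1.5.0: normexp background correction with the 770 negative control probes, an offset of 16, quantile normalization over the 12 arrays and log2. A probe entered where its detection p was under 0.05 on at least 3 of the 6 arrays of a cell line. The 31332 target names taken as genes exclude 3270 expressed sequence tag clusters, and each gene was represented by its probe with the highest mean. A linear model with 4 group means (8 residual degrees of freedom) gave moderated tests for the PC3-ML comparison, the LNCaP comparison, the shared effect of higher intended microRNA activity and the difference of the effects. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Where a group was not detected on any array, the fold is a lower bound against the level at which a probe is called detected on that group's arrays. Confidence intervals are 95% intervals from the moderated test. No replicate block was used in the main fit.

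A total of 26 gene lists written before the data were examined were tested with camera (preset correlation 0.01, at least 3 measured genes), with an estimated correlation and fry as alternatives, and Benjamini-Hochberg adjustment over lists. Target lists came from general knowledge of other studies, partly in other cell types. Named genes followed a rule fixed before the data were examined: up to 12 genes per direction with the largest changes among those past the threshold whose groups do not overlap, and, where fewer than 5 passed, further genes by p up to 5, given as not passing. From each list up to 4 members past the threshold or otherwise up to 2 with the smallest p could be named. HIP1R, the host locus genes and marker genes of the cell lines such as KLK3, VIM and CAV1 were fixed by name. Comparing genes between the experiments used Fisher's exact test, and 10000 random lists matched on expression were drawn for the target and cell cycle lists.

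The test was tried on simulated data with known changes. In each line 67 genes were changed by 0.5 log2 units, 67 by 1 and 66 by 2, all at once. In PC3-ML it recovered 34.3% of genes changed by 0.5 log2 units, 76.1% at 1 and 100% at 2, with 4 false calls, and in LNCaP 23.9%, 79.1% and 100% with 6 false calls. A simulated list of 28 genes shifted by -0.1 was called in 96% of 50 simulations and an unshifted list in none. A list was called here at an unadjusted camera p under 0.05, with the preset correlation. The simulated noise was independent between genes, so these simulations do not cover the effect of correlation between genes.

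Alternatives covered no background correction, scaling of array medians, normalization of each line alone, the submitters' deposited values, no or a stricter detection filter (detection p under 0.01 on all 6 arrays of the line), the mean of all probes, the arrays of a line alone, a replicate block, a trended robust prior, no moderation, array weights and leaving out each array in turn. The seed site test planned for both lines was not run, since no transcript sequence was at hand, and a slide block was not run, since the files name no slide. Values for the 92 external RNA control probes carried no signal: 2 of 1104 lay above the 95th percentile of the negative controls. Figures were drawn with matplotlib.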

Results

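Messenger RNA of human prostate cancer cell lines was measured on 12 Illumina HumanHT-12 v4 bead arrays in 4 groups of 3 arrays. PC3-ML, a metastatic subline of PC-3, received the microRNAs miR-23b and miR-27b or a scrambled control by viral transduction. LNCaP, a line from a lymph node metastasis, received antagomiRs, which are chemically modified inhibitors, against both microRNAs or a control antagomiR. Each array detected between 21211 and 22644 of its 47231 probes above the negative control beads. Log2 signals correlated across probes at r = 0.984 to 0.995 between arrays of 1 group and at r = 0.820 to 0.836 between the cell lines. The number of arrays limits the precision of every value, and values with ± are means with the SD of 3 arrays unless stated otherwise.

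KLK3, VIM and CAV1 separated the arrays of the cell lines as labelled (mean ± SD of the 6 arrays of a line in this paragraph). KLK3, which encodes prostate-specific antigen, lay at 11.60 ± 0.16 on the log2 scale in LNCaP and at 5.83 ± 0.13 in PC3-ML. VIM, the mesenchymal filament protein vimentin, lay at 14.65 ± 0.11 in PC3-ML and at 9.62 ± 0.14 in LNCaP. CAV1, a membrane scaffold protein, lay at 13.93 ± 0.18 in PC3-ML and was not detected on the LNCaP arrays by the same probe, at least 445-fold higher in PC3-ML by that probe. A second CAV1 probe lay at 10.39 and 10.49 in the 2 PC3-ML groups and at 5.21 and 5.19 in the 2 LNCaP groups, where it was detected on 2 of 3 control and 1 of 3 antagomiR arrays.

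Both PC3-ML replicate 3 arrays, 1 of each group, also carried transcripts typical of neural cells, which were chosen after their values were seen. FABP7, a brain fatty acid binding protein, lay at 8.42 and 9.01 there and at a mean of 4.66 on the other 4 PC3-ML arrays. SOX2, a neural stem cell transcription factor, lay at 6.88 and 7.33 against 5.01. Without both arrays the number of genes past the threshold was 3 in PC3-ML and 0 in LNCaP, as with them.

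**Figure D1:**
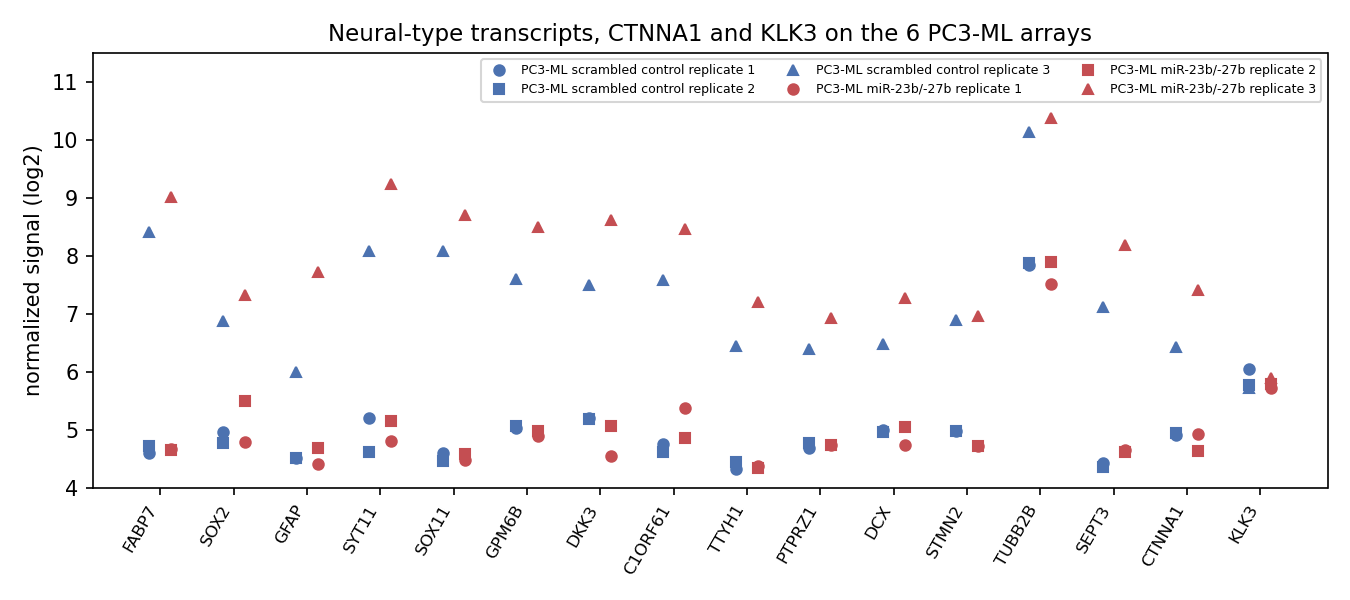
Normalized log2 signal of 14 neural-type genes, CTNNA1 and KLK3 on each of the 6 PC3-ML arrays; blue is scrambled control, red is miR-23b/-27b, and circles, squares and triangles are replicates 1, 2 and 3. For the 14 genes and CTNNA1 the triangles of both groups lie above the other 4 arrays, and for KLK3 they do not.

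The PC3-ML comparison asks which transcripts differ when both microRNAs are supplied. The probes for the microRNA genes themselves rose most. The MIR23B probe was not detected on the scrambled control arrays (4.59 ± 0.05) and reached 13.63 ± 0.20 on the microRNA arrays, at least 368-fold higher (adjusted p = 1.36e-13, limma). The MIR27B probe went from 4.55 ± 0.05, also not detected, to 12.07 ± 0.39, at least 125-fold higher (adjusted p = 1.79e-11). C9ORF3, the protein-coding gene whose intron holds both microRNAs, had a log2 difference of 0.002 with a 95% confidence interval from -0.47 to 0.48. Probes for the related precursors MIR23A, MIR27A, MIR24-1 and MIR24-2 were not detected on any of the 12 arrays, and FANCC, the neighbouring gene, was detected on too few PC3-ML arrays to be tested.

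**Figure D2:**
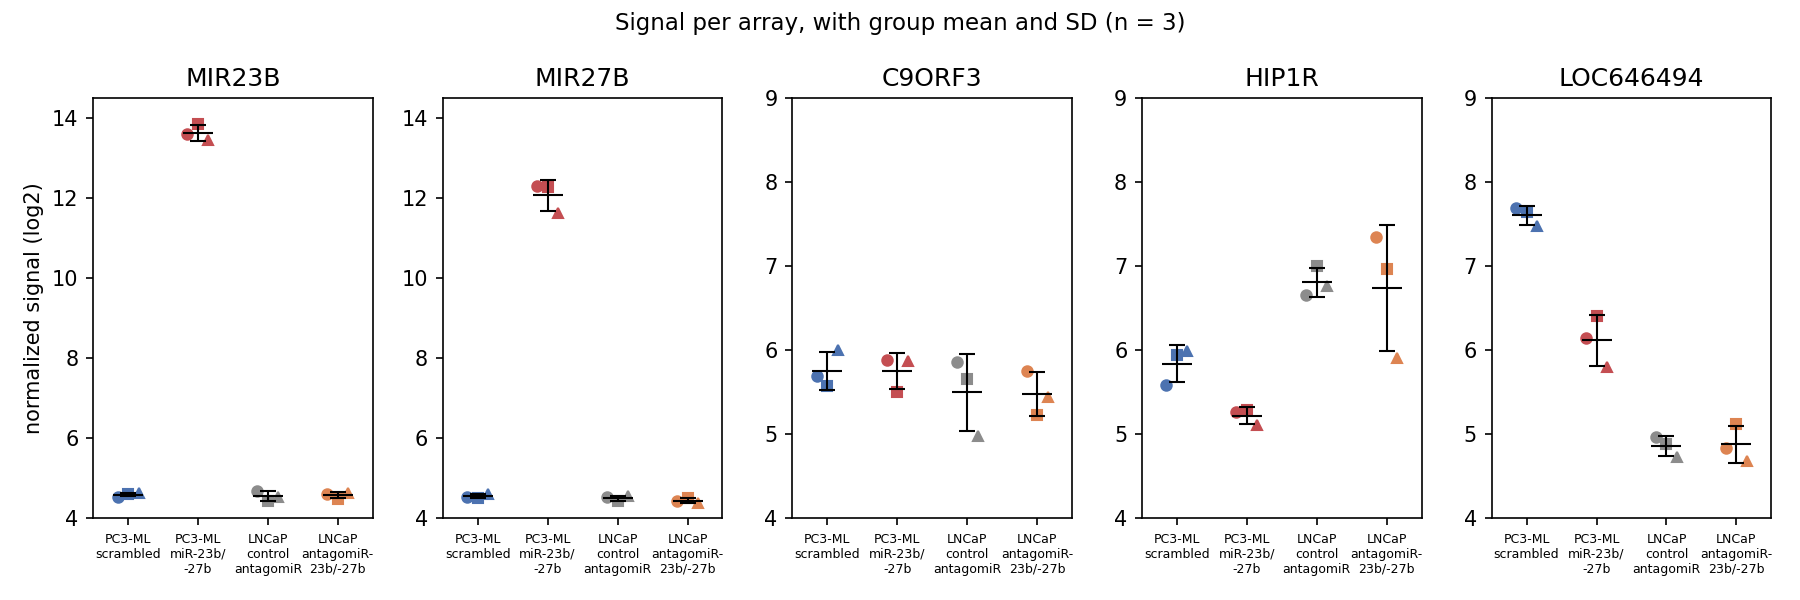
Normalized log2 signal of 5 genes on each of the 12 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, and black bars are the group mean and SD. MIR23B and MIR27B lie near 4.5 on 9 arrays and above 11.6 on the 3 PC3-ML microRNA arrays; C9ORF3 shows no such separation, and HIP1R and LOC646494 are lower on all 3 PC3-ML microRNA arrays than on the scrambled arrays.

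Of 15631 genes tested in PC3-ML, 3 passed an adjusted p of 0.05, 2 higher and 1 lower. The lower one was LOC646494, which the deposited table places on chromosome 18 and which has no current symbol. It fell from 7.60 ± 0.11 to 6.12 ± 0.30, a log2 change of -1.49 (SE 0.16, adjusted p = 0.00329), and lay lower on 3 of 3 arrays. Its call was lost on the submitters' deposited values (adjusted p = 0.0824) and in a fit of the PC3-ML arrays alone (adjusted p = 0.0993), with log2 changes of -1.51 and -1.49. At an unadjusted p under 0.05 there were 527 genes, or 3.37%, fewer than the 5% that chance gives. In 1408 genes (9.01%) the 3 arrays of each group did not overlap, where chance gives 10%.

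The next genes by p did not pass. The higher ones were LOC648638 with a log2 difference of 0.74, LOC100131435, and CCDC72 (now TMA7, a protein linked to translation) with 0.49, each at an adjusted p of 0.588. LOC100131435 was detected on the microRNA arrays and not on the scrambled ones, which gives at least 1.19-fold. The lower ones were SCARNA14, a small Cajal body RNA, at -0.93 (adjusted p = 0.588), F8, coagulation factor VIII, at -0.52, and KIRREL (now KIRREL1), a cell adhesion protein, at -0.76 (both adjusted p = 0.623). LOC100134360 was at -0.64 (adjusted p = 0.874).

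Genes that other studies had reported as targets of the 2 microRNA families shifted lower together in PC3-ML, by small amounts. Among reported miR-27 targets, 22 of 27 measured genes were lower and 5 higher, with a median log2 change of -0.11 (camera adjusted p = 0.00192; with an estimated correlation adjusted p = 0.148). Among reported miR-23 targets, 21 of 28 were lower and 7 higher, with a median of -0.074 (camera adjusted p = 0.00442; with an estimated correlation adjusted p = 0.0928). The medians were negative on each of the 3 microRNA arrays for both lists. In the main fit no single target passed, over all genes or adjusted over the list alone, and with array weights CCNG1 passed over all genes. The examples taken by the fixed rule were CCNG1 (cyclin G1, a p53 target on both lists) at -0.44, XIAP (a caspase inhibitor) at -0.37 and DPYD (which degrades pyrimidines) at -0.23, each with an adjusted p of 1. The lists share 4 measured genes. With the correlation between genes estimated from the data in place of the preset one, both calls were thus lost. Without PC3-ML miR-23b/-27b replicate 1 the preset test gave adjusted p = 0.132 and adjusted p = 0.113, with medians of -0.062 and -0.089. That array had the lowest signal of the 18S ribosomal RNA probe in PC3-ML, 9.03 against 10.70 to 11.64 on the other 5.

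Cell cycle genes shifted higher in PC3-ML: 38 of 50 were higher and 12 lower, with a median log2 change of 0.068 (camera adjusted p = 0.00192; with an estimated correlation adjusted p = 0.0545). None passed on its own or adjusted over the list alone. The examples were MKI67, the proliferation marker Ki-67, at 0.33 and CCNB2, a mitotic cyclin, at 0.27. The list of genes typical of PC3 cells was also shifted higher, 11 of 14 genes with a median of 0.098 (camera adjusted p = 0.0368), and the call was lost with an estimated correlation (adjusted p = 0.148). Its examples were LGALS1 (galectin-1) at 0.26 and TGFBI (an extracellular matrix protein) at 0.21. The host locus list, made up here of MIR23B, MIR27B and C9ORF3, was the fifth call and held with an estimated correlation (adjusted p = 0.000387). It rests on the microRNA probes.

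**Figure D3:**
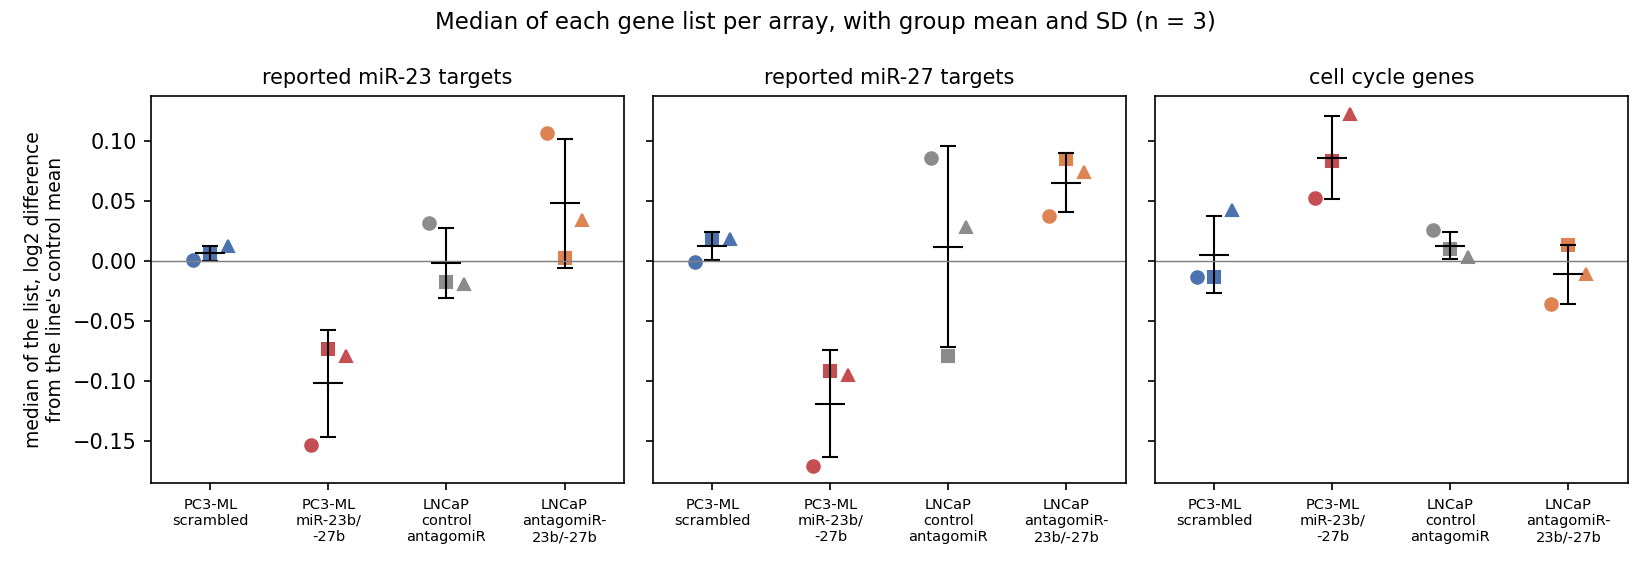
Median over each gene list of the log2 difference between an array and the mean of its cell line's control arrays, for the 12 arrays; circles, squares and triangles are replicates 1, 2 and 3, and black bars are the group mean and SD of the array medians. Both target lists lie below 0 on the 3 PC3-ML microRNA arrays and the cell cycle list above 0.

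The other 21 lists did not pass in PC3-ML, with adjusted p from 0.111 to 0.922. Clathrin endocytosis had 19 genes higher and 9 lower, among them the adaptor subunit AP2S1 at 0.16, and its median and mean differed in sign. Glutamine and proline metabolism had 4 higher and 11 lower, with PPAT, an enzyme of purine synthesis, at -0.23. Cholesterol synthesis had 6 higher and 18 lower, with EBP at 0.29 and SC4MOL (now MSMO1) at -0.32, and fatty acid and lipid metabolism had 8 higher and 20 lower, with CPT1A, which carries fatty acids into mitochondria, at -0.33. Epithelial genes split 10 higher to 9 lower, mesenchymal genes 16 to 7, TGF-beta response 12 to 14, p53 targets 10 to 13 and NF-kappaB targets 12 to 12. Interferon response split 22 to 19, unfolded protein and ATF4 response 17 to 17, hypoxia and glycolysis 13 to 19, microRNA pathway genes 5 to 10, ribosomal protein genes 25 to 15 and oxidative phosphorylation genes 25 to 14. The lists for other cell types were neuroendocrine genes (3 to 5), fibroblast genes (4 to 3), blood and endothelial genes (1 to 5) and genes typical of LNCaP (5 to 4). Median and mean, or median and test, also differed in sign for other lists near 0, such as interferon response, hypoxia and glycolysis, TGF-beta response, and unfolded protein and ATF4 response.

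HIP1R, a clathrin and actin binding protein of endocytosis, was named before the data were examined because the published study of these cells followed it. That choice is not independent of the study. HIP1R was lower on 3 of 3 microRNA arrays in PC3-ML. Its signal was 5.84 ± 0.22 with scrambled control and 5.22 ± 0.10 with the microRNAs, a log2 difference of -0.62 (SE 0.28, 95% confidence interval -1.22 to -0.01). It did not pass over all genes (limma, unadjusted p = 0.0456, adjusted p = 1). The SE and p rest on a spread shared by all 4 groups, of which the LNCaP antagomiR arrays had the largest (6.74 ± 0.75). They thus do not describe the spread of the PC3-ML arrays alone. The size of the PC3-ML difference was -0.27 without background correction. The other 3 HIP1R probes were not detected on any PC3-ML array. In the authors' deposited table the ratio of means was 0.498 with a p-value of 0.0160. In LNCaP the log2 difference with the antagomiRs was -0.068 (SE 0.28, 95% confidence interval -0.67 to 0.54, unadjusted p = 0.810), and its sign changed without LNCaP antagomiR-23b/-27b replicate 3 (0.35). The difference between the cell lines in the microRNA effect on HIP1R was -0.69 (SE 0.39, unadjusted p = 0.106, adjusted p = 1.00).

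The LNCaP comparison asks which transcripts differ with antagomiRs meant to inhibit the cells' own microRNAs. No gene of 15439 tested passed with limma (smallest adjusted p = 1.00), 402 genes (2.60%) had an unadjusted p under 0.05, and the groups did not overlap in 854 genes (5.53%, against 10% by chance). The MIR23B and MIR27B probes were not detected on any LNCaP array, nor on the scrambled PC3-ML arrays. The microRNAs themselves were not measured, so this does not show that LNCaP lacks them. C9ORF3 had a log2 difference of -0.025 and FANCC of -0.098. On simulated data the same test recovered 79.1% of LNCaP genes changed by 1 log2 unit and 23.9% of those changed by 0.5. Many genes were changed at once there, which eases the Benjamini-Hochberg threshold. Recovery would be lower where few genes change, so these shares overstate what the LNCaP comparison could find in that case.

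The LNCaP genes with the smallest p, none past the threshold (adjusted p = 1.00 for each), were mixed in function. Higher with the antagomiRs were BPTF, a subunit of a chromatin remodelling complex, at 0.59, PLCH2, a phospholipase C, at 0.54, and LOC100134121 at 0.47. Within LNCaP, C9ORF126 (now SCAI, a suppressor of cell invasion) and LOC100128507 were detected only with the antagomiRs, at least 1.37-fold and 1.25-fold. Lower were TBXAS1, thromboxane synthase, at -0.58, CISD3, a mitochondrial iron-sulfur protein, at -0.57, and LCORL, a DNA-binding protein, at -0.55. CEP170, a centrosomal protein, and LOC441054 were, within LNCaP, detected only on the control arrays, at least 1.48-fold and 1.32-fold lower.

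None of 25 gene lists passed in LNCaP. Reported miR-23 targets were 14 higher and 10 lower (median 0.0081) and reported miR-27 targets 15 higher and 12 lower (median 0.021, camera adjusted p = 0.746 for both). Their examples were IL6R at -0.32, SMAD5 at 0.18, ST14 (matriptase) at -0.36 and VDR (the vitamin D receptor) at -0.49. Oxidative phosphorylation genes had the smallest p, with 28 of 39 lower, among them NDUFA2 at -0.20 and COX7A2 at -0.17 (camera adjusted p = 0.646). Cholesterol synthesis genes were 17 higher and 6 lower, with HSD17B7 at 0.22. Clathrin endocytosis split 13 to 13, with ITSN2 at -0.33 and HIP1 at -0.40. Cell cycle genes split 22 to 28.

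By the labels one experiment was meant to raise microRNA activity and the other to lower it, and their effects were averaged in the direction of higher intended activity. The arrays do not show the inhibition itself. Of 13771 genes tested in both lines, none passed for this shared effect (377 at an unadjusted p under 0.05, limma) and none for the difference between the lines (316). Reported miR-23 targets were lower with higher intended activity in 20 of 23 genes (median -0.086, camera adjusted p = 0.00774; with an estimated correlation adjusted p = 0.0993). Reported miR-27 targets were lower in 17 of 22 (median -0.073, camera adjusted p = 0.00952; with an estimated correlation adjusted p = 0.361). Cell cycle genes were higher in 34 of 50 (median 0.047, camera adjusted p = 0.00952; with an estimated correlation adjusted p = 0.0993). The examples were CCNG1 at -0.23, CHUK (an NF-kappaB pathway kinase) at -0.21, ADORA2B (an adenosine receptor) at -0.28, MKI67 at 0.24 and CDC25A (a cell cycle phosphatase) at 0.13. Without PC3-ML miR-23b/-27b replicate 1 the miR-27 list had adjusted p = 0.0773, and without PC3-ML miR-23b/-27b replicate 3 the cell cycle list had adjusted p = 0.103. None of 23 lists differed between the lines (smallest adjusted p = 0.147). In LNCaP alone the target and cell cycle lists each had camera adjusted p = 0.746. An average can pass through 1 line, so these calls do not show an effect in both.

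No gene passed in both experiments, in either pair of directions. At an unadjusted p under 0.05 in both, 23 genes were found where 8.12 were expected, of which 8 moved in opposite directions and 15 in the same direction. The excess was clearest for genes lower in both, 9 against 2.01 expected (Fisher's exact test, p = 0.000186). Genes higher in both were 6 against 2.05. Genes lower in PC3-ML and higher in LNCaP were 6 against 2.11, and the converse 2 against 1.96. The expected counts and the test take the 2 p-values of a gene as independent. Both comparisons share each gene's variance estimate, so a spread estimated too low gives a small p in both. The excess thus does not show a common response. Across genes the log2 changes of the 2 experiments correlated at r = -0.075, and genes are not independent replicates. By the authors' deposited values, 914 probes in PC3-ML and 528 in LNCaP had a p-value under 0.05, and none remained after a Benjamini-Hochberg adjustment of those values.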

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

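The tests in this part on the effect of the microRNAs on neural transcripts, on LNCaP detection of those transcripts, on the source of the microRNA probe signal and on leaving out replicate 3 were chosen after the result was seen.

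A signal appeared among the expressed sequence tag clusters, which the gene counts leave out. HS.225083, on chromosome 1 in the deposited table, was not detected on the 3 scrambled PC3-ML arrays (4.75 ± 0.08) and was detected on the 3 microRNA arrays (6.67 ± 0.23), at least 2.95-fold higher (limma, adjusted p = 1.09e-05 over 1159 clusters). On the LNCaP arrays it lay at 5.55 ± 0.30 (SD, 6 arrays) and was detected on 5 of 6. No other cluster passed in PC3-ML and none of 1126 in LNCaP, with 91 and 63 at an unadjusted p under 0.05.

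Transcripts typical of neural and glial cells stood out on replicate 3 of both PC3-ML groups. FABP7 lay at 8.42 on the scrambled and 9.01 on the microRNA replicate 3 array, against a mean of 4.66 on the other 4 PC3-ML arrays, and SOX2, GFAP, SOX11 and DCX did likewise. In a list of 61 neural and glial genes written before their values were seen, the median excess was 0.22 and 0.41 log2 units. That was above all of 10000 matched random lists on both arrays (percentile 100). The theme of the list came from the neural genes first noticed on these arrays, so the list is not independent of them. RNA of neural-type cells in both arrays is a candidate source. Of those 61 genes 22 are detected on all 4 other PC3-ML arrays, and 10 and 18 were raised by over 1 log2 unit, while SOX10, S100B and OLIG1 stayed near the floor. An effect of the microRNAs is argued against by the scrambled array, where the 14 genes first noticed exceeded the other scrambled arrays by a median of 2.29. RNA of the LNCaP arrays as the only source is argued against, since 9 of the 14 were detected on no LNCaP array. LNCaP RNA in addition to another source is not decided. A set of 40 genes was bright in LNCaP and absent from the other PC3-ML arrays. Of these, 25% were raised by over 1 log2 unit on the microRNA replicate 3 array, against 0.60% of all genes. On the scrambled replicate 3 array 4 of the 40 were raised, against 0.18% of all genes. The 25% lay between the shares set beforehand for and against LNCaP RNA. The median excess of the 40 on the microRNA replicate 3 array was 0.11, and KLK3 was not raised (5.73 and 5.90 against 5.83). CTNNA1, known to be deleted in PC-3 cells, lay at 6.44 and 7.42 against 4.86, and no biological explanation beyond the microRNAs was tested.

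The MIR23B and MIR27B probes rose in PC3-ML while C9ORF3 did not follow. Higher transcription of the cells' own locus is argued against by the upper 95% limit of the C9ORF3 change, 0.478, although a primary transcript can differ from its host messenger RNA. Transcripts of the introduced construct remain open and were not tested.

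The target lists and cell cycle genes shifted in PC3-ML. With the mean of the 18S and 28S ribosomal RNA probes as a covariate, the miR-27 targets kept a camera p of 0.000656. Their median was -0.092 against -0.114 without the covariate. The covariate differed little between the PC3-ML groups (mean -0.093 with the microRNAs and 0.093 with scrambled control, SD 1.07 and 0.35). It could thus remove little of a shift between the groups and does not decide on RNA quality or labelling. Without both PC3-ML replicate 3 arrays the camera p was 0.000103, which argues against RNA of another cell type in them. What stays open is RNA quality or labelling, the dependence on PC3-ML miR-23b/-27b replicate 1, without which the camera p was 0.0265, and the correlation between genes. A microRNA effect may account for the lists, as a hypothesis.

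For PC3-ML, 1 of the 10 splits of the 6 arrays gave as many genes as the real one (3 genes, highest other split 0), and 1 of 10 gave as many lists (5 lists, highest other 0). In LNCaP all 10 splits gave as many genes and lists (0, highest other 0), which is certain for a count of 0. Splits of 3 against 3 are too few for a share under 0.05. Over 100 splits of both lines, the shared gene count of 0 was matched by 100 (highest other 0). The count of differing genes of 0 was also matched by 100 (highest other 1). Every split matches a count of 0, so these counts decide nothing. An absolute correlation of 0.0753 or more came up in 77 splits (highest other 0.541), so chance is not excluded for the correlation. The shared shift had as small a camera p in 2 splits for miR-23 targets (real 0.000337, smallest other 0.000146). It did in 2 for miR-27 targets (0.00104, 0.000676) and in 3 for cell cycle genes (0.00124, 0.000494), each a share under 0.05. These are the lists that passed for the shared effect, and the shares are not corrected for that choice, so chance is not excluded. A median as large came up in 2, 13 and 3 of the 100 splits, a share over 0.05 for the miR-27 targets. With the real PC3-ML grouping kept, however, 2, 3 and 3 of 20 LNCaP groupings gave as small a p, so the splits do not show what the LNCaP arrays add.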

How the results depend on the processing

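The alternatives chosen after the data were seen were leaving out both PC3-ML replicate 3 arrays and the ribosomal RNA covariate. The cause of each change below was not tested unless stated. The PC3-ML gene count of 3 stayed between 2 and 4 except for 1 gene with a detection p under 0.01 on all arrays, a filter that removes MIR23B and MIR27B since they are undetected in controls, and 18 genes with array weights. LOC646494 missed the threshold on the submitters' deposited values, on the arrays of its line alone and without moderation. SCARNA14 passed without LNCaP control antagomiR replicate 2 (adjusted p = 0.0348), CCDC72 with the trended robust prior, and CCDC72, SCARNA14, LOC100131435, LOC100134360 and CCNG1 with array weights. LNCaP stayed at 0 genes and 0 lists in every alternative run. With no detection filter, 2 genes passed for the shared effect and 2 for the difference. The count of genes in opposite directions stayed at 0 and the correlation within 1 SD of the splits (0.226). No scaling moved the median of all genes by over 0.1 log2 units.

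HIP1R in PC3-ML did not pass in any alternative and was lower in each with its main probe, from -0.74 to -0.54 when 1 array was left out; 2 undetected probes gave 0.21 and 0.19. In LNCaP it was 0.16 with array weights, 0.25 and 0.17 for 2 other probes, and -0.37 to 0.35 when 1 array was left out. C9ORF3 was -0.060 in PC3-ML with array medians scaled, and -0.090 to 0.127 there and -0.285 to 0.154 in LNCaP when 1 array was left out. ADAM7 in LNCaP was -0.031 without LNCaP control antagomiR replicate 2, in a range from -0.031 to 0.410. Leaving out HIP1R, 975 of 984 alternative values for 55 gene results kept their direction.

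The PC3-ML list count of 5 was 7 with array medians scaled, 1 with an estimated correlation and 3 with fry, 2 of the 5 and mesenchymal genes (0.0268), and ranged from 2 to 5 when 1 array was left out. With an estimated correlation, adjusted p was 0.0545 for cell cycle genes, 0.148 for PC3-type genes, 0.0928 for miR-23 targets and 0.148 for miR-27 targets. With fry, PC3-type genes had 0.156, miR-23 targets 0.0520 and miR-27 targets 0.189. PC3-type genes also missed the threshold on the submitters' values (0.0667), with a replicate block (0.0519), without both replicate 3 arrays (0.0723) and with the ribosomal RNA covariate (0.0717). Leaving out 1 array gave 0.0180 to 0.184 for PC3-type genes, 0.00372 to 0.113 for miR-23 targets, 0.000382 to 0.132 for miR-27 targets and 0.00192 to 0.0382 for cell cycle genes. PC3-type genes missed it without PC3-ML scrambled control replicate 3 (0.0840), PC3-ML miR-23b/-27b replicate 1 or LNCaP control antagomiR replicate 2 (0.0565).

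With a replicate block the PC3-ML gene count stayed at 3 and the list count was 4. Residuals of arrays with equal numbers correlated at 0.093, 0.12 and 0.35 in PC3-ML and at -0.32, -0.14 and 0.24 in LNCaP, not all over 0.1, and not every array correlated best with its own number, so the numbers were not taken to pair the arrays.

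The shared list count of 3 was 6 without background correction, 6 with array medians scaled, 5 with the stricter filter, 0 with an estimated correlation, 0 with fry and 2 to 5 when 1 array was left out. Cell cycle genes had adjusted p = 0.0993 with an estimated correlation and 0.136 with fry, miR-23 targets 0.0993 and 0.0851, and miR-27 targets 0.361 and 0.372. Leaving out 1 array gave 0.00460 to 0.103 for cell cycle genes, 0.00261 to 0.0481 for miR-23 targets and 0.00261 to 0.0773 for miR-27 targets. In LNCaP the target lists changed direction when 1 array was left out, with adjusted p from 0.678 to 0.930 for miR-23 and from 0.757 to 0.910 for miR-27 targets. Dim probes limit all of this: MIR24-1 was not detected on any array, and most HIP1R probes were detected on no PC3-ML array and on few or no LNCaP arrays.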

Other observations

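On PC3-ML replicate 3 of both groups, 52 genes were raised by over 1 log2 unit on both arrays relative to the other 4 PC3-ML arrays, while every other pair of a scrambled and a microRNA array had 0 such genes. They include SYT11 (a synaptic vesicle protein, 8.09 and 9.23), SOX11 (8.08 and 8.71), TUBB2B (a neuronal tubulin, 10.13 and 10.37, detected on all 6 PC3-ML arrays) and NNAT (neuronatin, 7.57 and 8.02). Among them 33 were not detected on any of the other 4 arrays, and no gene was lowered by over 1 log2 unit on both. The genes were chosen after their values were seen.

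The 18S ribosomal RNA probe varied from 7.17 on LNCaP control antagomiR replicate 2 to 11.64 on PC3-ML scrambled control replicate 3, with 9.22 on LNCaP antagomiR-23b/-27b replicate 1. The first axis of variation within groups held 39.7% of the variance, and its highest scores were those of LNCaP control antagomiR replicate 2 and PC3-ML miR-23b/-27b replicate 1, and its lowest that of PC3-ML miR-23b/-27b replicate 3. Array weights for these 3 arrays were 0.242, 0.534 and 0.309.

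Among matched random lists, the PC3-ML median of the miR-27 targets lay at percentile 0.06, that of the miR-23 targets at 1.31 and that of the cell cycle genes at 99.95. In LNCaP the same lists lay at percentiles 65.6, 49.7 and 17.9. The random lists do not keep the correlation between the genes of a list. All of these lists had passed in PC3-ML on the same data, so the PC3-ML percentiles are not independent support.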
